A study of Mus musculus with 13 samples.

How the data were processed

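Total RNA of liver was extracted with TRIzol per the labels, and 250 ng were labelled with biotin by the WT Plus protocol and hybridised to Affymetrix mouse gene arrays. Per the submitters' processing notes, the authors computed the deposited log2 values with the robust multi-array average (RMA) in Affymetrix Expression Console, with no versions given. The values held 41345 probe sets in 13 arrays, 4 of HFD, 4 of CANA and 5 of CR. Scanner files and detection p-values were not used here, and the number of arrays limits the precision.

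Probe sets were named through the platform's annotation, with Entrez identifiers matched to a RefSeq table for 23328 of the 23521 probe sets with exactly 1 gene symbol. Probe sets with several symbols (1814) or none (16010) were left out of the comparisons. Of 22180 genes, 1082 had several probe sets, and the one with the highest mean over all arrays was taken. Genes with a mean below the 40th percentile were left out as dim, which left 13308 genes with means of at least 3.95.

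The groups were compared with limma 3.58.1 in R 4.3.3, in a single fit to all 13 arrays without covariates, with 10 residual and 5.71 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Adjusted p values of genes are those of limma, and those of lists are of limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Of 48 gene lists, the 45 with at least 5 tested genes were tested. Camera with an estimated correlation, and fry, were run beside it. The median estimated correlation was 0.195.

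The comparisons, thresholds, gene lists, most other settings and the rule for named genes were chosen before the data were examined. The rule took the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap, without predicted or unnamed loci. Where no gene was called it took the 5 highest and 5 lowest by moderated t. It added up to 4 members with the smallest p of each list that passed or held a called gene, and 16 genes of the drug target, glucose, lipid and hormone pathways in every comparison. Genes among these are named where a sentence describes their group. Some genes that the rule takes are not reported here.

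The other settings tried were other filters on dim genes, another normalization, centring on the median, other variance models, array weights, the mean of probe sets, an adjusted p of 0.10, only the arrays compared, the replicate number as a block, the serial number as a covariate, and leaving out each array in turn. The settings with the serial-number sets were added after the data were seen.

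The pipeline was tested on simulated data with independent noise in each gene and 200 changed genes in each of 5 runs per comparison. Of changes of 0.5 on the log2 scale 54.0, 57.0 and 57.6% were called in CANA vs HFD, CR vs HFD and CANA vs CR, and 98.2% of changes of 1 in each. False calls made up 5.83, 4.49 and 4.05% of the calls. Without changes, 2 of 5 runs of CANA vs HFD had 1 call, and no run of the others had any.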

Results

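Liver RNA of male C57Bl/6J mice was profiled on 13 Affymetrix mouse gene arrays. Per the labels, the mice were 6 weeks old when a diet with 60% fat began, and all 3 groups ate it for 4 weeks to become obese. For 4 further weeks, the mice of 4 arrays stayed on the diet (HFD), those of 4 received canagliflozin at 25 to 30 mg/kg on the same diet (CANA), and those of 5 were calorie-restricted by 15 to 30% to match the weight of the treated mice (CR). Canagliflozin inhibits SGLT2, the sodium-glucose cotransporter of the kidney tubule, and causes glucose loss in urine. The CR group serves to set effects of the drug apart from those of lower weight. It also differs in food intake, and no weights were examined here. The log2 values of the arrays had medians between 4.07 and 4.13, and any pair of arrays correlated at 0.977 to 0.989 across genes. The number of arrays limits the precision, and the values carry no read depth. After dim genes were left out, 13308 genes were tested. Slc5a2, the gene of SGLT2, lay near the lower limit of the tested range of 3.95, at 4.30 ± 0.12 in HFD, 4.20 ± 0.20 in CANA and 4.35 ± 0.21 in CR (SD, n = 4, 4 and 5). Its CANA minus HFD difference was -0.10 with a limma adjusted p of 0.893. The labels say nothing more on whether each array came from a separate animal, so the p-values measure the spread between these samples. Slc5a1 was below the filter, and Gdf15 was not analysed here.

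The arrays also carried a serial number in their labels, and they differed by it. The first principal component, with 18.9% of the variance, correlated with the serial number at a Pearson r of 0.707 (n = 13, two-sided permutation p = 0.00778). It averaged -7.55 ± 8.30 over the 7 arrays numbered 1 to 8 and 8.81 ± 5.54 over the 6 numbered 9 to 14 (SD). Within these sets r was 0.208 and -0.209, so the change lay between the sets more than along the numbers inside them. Without the 2 arrays farthest from the median serial number r was 0.567 (permutation p = 0.0712). Small nucleolar RNA genes, which guide the modification of ribosomal RNA, averaged 0.247 ± 0.288 and -0.288 ± 0.138 around their gene means in the same sets. The sets and this class of genes were chosen after the values were seen, so no test is given for them. Every group had arrays in both sets. Among the 50 genes that followed the serial number in limma, 18 were small nucleolar RNA genes. By camera, 14 of 45 gene lists also moved with the serial number, 9 of them named in the comparisons below. Higher at later numbers were cholesterol synthesis (median slope 0.07, adjusted p = 1.46e-18), glucocorticoid targets (0.04, adjusted p = 2.13e-07), fatty acid synthesis (0.03, adjusted p = 3.37e-04), PPAR-alpha targets (0.02, adjusted p = 0.0014), xenobiotic metabolism (0.01, adjusted p = 0.039) and gluconeogenesis (0.01, adjusted p = 0.045). None of the lists passed with an estimated correlation (lowest adjusted p = 0.155). Lower at later numbers were oxidative phosphorylation (-0.01, adjusted p = 2.37e-04), ER chaperones (-0.02, adjusted p = 0.012) and male-biased genes (-0.02, adjusted p = 0.039), with an adjusted p of at least 0.825 with an estimated correlation.

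**Figure D1:**
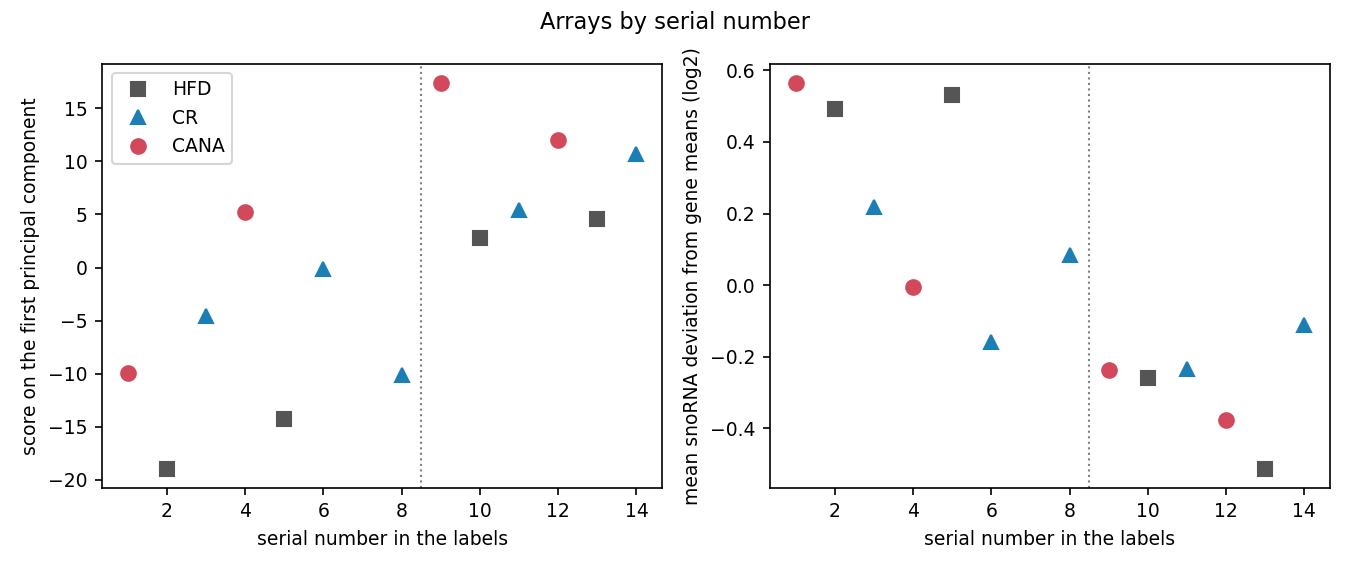
Score on the first principal component and mean deviation of small nucleolar RNA genes on the log2 scale (vertical axes) of each array (points, shaped and coloured by group) against the serial number in the labels (horizontal axes), with a dotted line between 8 and 9. The mean deviation is 0.247 over the arrays to the left and -0.288 over those to the right.

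The first comparison asked what canagliflozin changed against the continued diet. The livers of treated mice had higher Igfbp1, Lepr and Cyp4a31 and lower Fasn, Ppp1r3c and Thrsp. Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, rose from 8.64 ± 0.27 in HFD to 11.23 ± 0.93 in CANA (log2, SD, n = 4 each), which is 6.02-fold (difference 2.59, SE 0.46, limma adjusted p = 0.038). Lepr, the leptin receptor, rose 5.46-fold, from 4.25 ± 0.29 to 6.70 ± 0.57 (adjusted p = 0.0023). The HFD level lay near the lower limit of the tested range, so the size of this rise is uncertain. Cyp4a31, one of the fatty acid hydroxylases of the cytochrome P450 4A family, rose 4.45-fold (2.15, SE 0.30, adjusted p = 0.011). Its near-identical family members can share probes, so its value is uncertain between paralogs. Fasn, the fatty acid synthase, dropped by 1.41 on the log2 scale (SE 0.20, adjusted p = 0.011), from 10.20 ± 0.36 to 8.78 ± 0.40. Thrsp, a regulator of lipogenesis, dropped by 1.00 (SE 0.18, adjusted p = 0.038), from 11.41 ± 0.20 to 10.41 ± 0.28.

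In all, 22 genes passed an adjusted p of 0.05 in the limma fit, 17 higher and 5 lower. Of all tested genes, 652 (4.90%) had no overlap between the arrays of the groups, where chance gives 2.86%. Rises past the threshold included Sik1, a salt-inducible kinase (1.41, adjusted p = 0.033), and Ctcflos (1.31, adjusted p = 0.013). They also included Tbc1d8 (1.04, adjusted p = 0.016), the mitochondrial glutamate carrier gene Slc25a22 (0.99, adjusted p = 0.049) and Nnmt, the nicotinamide N-methyltransferase (0.83, adjusted p = 0.038). Slc22a5, the carnitine transporter, rose by 0.89 (adjusted p = 0.038), and Fh1, the fumarate hydratase of the citric acid cycle, rose by 0.72 (adjusted p = 0.015). The glycogen-targeting subunits of protein phosphatase 1 moved apart. Ppp1r3g rose by 1.41, from 4.58 near the lower limit (SE 0.26, adjusted p = 0.047), and Ppp1r3c fell by 1.41 (SE 0.24, adjusted p = 0.037). Another subunit gene, Ppp1r3b, differed by -0.83 without passing (adjusted p = 0.185), and by -0.78 in its other probe set, which was not used (unadjusted p = 2.06e-04). Ppp1r3g and Ppp1r3c were the called members among the 10 genes of the glycogen list, which as a list did not pass (camera adjusted p = 0.0974). At an adjusted p of 0.10 the count was 56, and 1174 genes had an unadjusted p under 0.05, against 665 expected by chance.

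**Figure D2:**
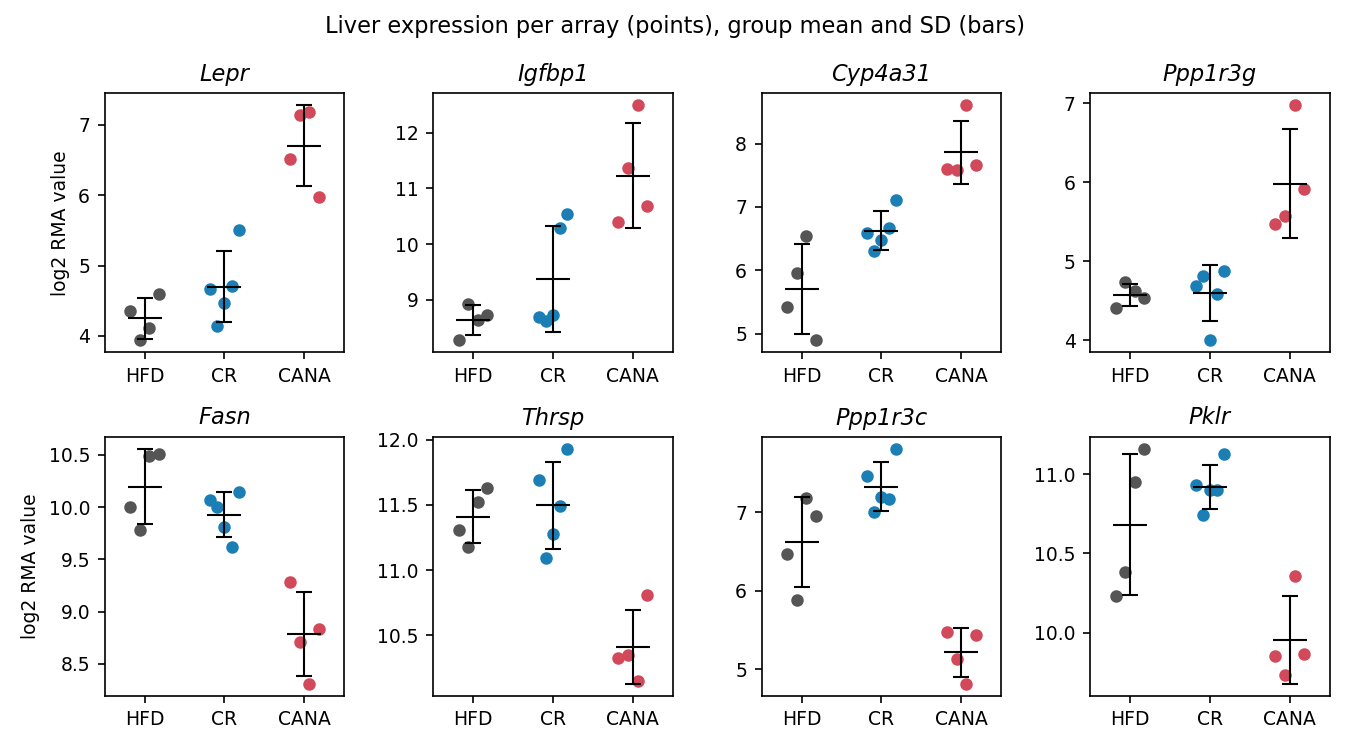
Log2 RMA values (vertical axis) of 8 genes in each of the 13 arrays (points) by group (horizontal axis), with the group mean and SD as black bars. Lepr sits at a mean of 6.70 in CANA against 4.25 in HFD, and Ppp1r3c is lowest in CANA at 5.21.

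Fatty acid synthesis genes were lower under canagliflozin. Of 18 tested members, 15 were below zero, with a median difference of -0.37; 2 were called over all genes (Fasn and Thrsp, both lower) and 7 adjusted over the list alone. The list passed camera (adjusted p = 2.17e-08) but not with an estimated correlation (adjusted p = 0.289). Scd1, the stearoyl-CoA desaturase, differed by -1.36 (SE 0.27, adjusted p = 0.061), and Srebf1, the gene of the lipogenic factor SREBP-1, by -0.85 (adjusted p = 0.108). Mid1ip1 differed by -0.87 (adjusted p = 0.095), but its other probe sets gave 0.23 and 0.04. The cholesterol synthesis list was lower by camera (median -0.32, 16 of 19 members below zero, adjusted p = 0.0035), with no member called over all genes or adjusted over the list alone. With an estimated correlation its adjusted p was 0.689. Its leading members were Stard4, a sterol carrier (-0.55, adjusted p = 0.263), and Lss, the lanosterol synthase (-0.84, adjusted p = 0.545). The glycolysis and fructolysis list was lower (median -0.15, 9 of 11 members below zero, camera adjusted p = 0.025, and adjusted p = 0.289 with an estimated correlation). None of its members was called over all genes, while 3 were adjusted over the list alone, 2 lower and 1 higher. Pklr, the liver pyruvate kinase, differed by -0.73 (adjusted p = 0.166) and Khk, the fructose kinase, by -0.49 (adjusted p = 0.286), whereas Txnip differed by 0.80 (adjusted p = 0.337).

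Lists of fat oxidation were higher. Among 27 PPAR-alpha target genes, 22 were above zero (median 0.29, camera adjusted p = 7.2e-10), with 1 called over all genes, Cyp4a31, and 7 adjusted over the list alone. With an estimated correlation the adjusted p was 0.318. Cyp4a14, another cytochrome P450 4A gene that can share probes with its relatives, had a difference of 3.51 with a wide SE of 0.89 (adjusted p = 0.166). Fgf21, a fasting-induced liver hormone, differed by 1.22 (SE 0.25, adjusted p = 0.065), and Slc27a1, a fatty acid transporter, by 0.84 (adjusted p = 0.138). Pdk4, the pyruvate dehydrogenase kinase, had a 2.83-fold higher mean without passing (SE 0.46 on the log2 scale, adjusted p = 0.265). Its log2 difference ran from 0.83 to 2.07 over the alternative fits. For mitochondrial fatty acid oxidation, 19 of 20 members were above zero (median 0.16, camera adjusted p = 1.37e-06, and adjusted p = 0.289 with an estimated correlation). Slc22a5 was its member called over all genes and the 1 called adjusted over the list alone. Cpt1a, which admits long-chain fatty acids to mitochondria, was at 0.29 (adjusted p = 0.572). The lipid droplet and PPAR-gamma list was higher (median 0.31, 13 of 17 above zero, camera adjusted p = 4.99e-05), though not with an estimated correlation (adjusted p = 0.424). It had no gene called over all genes and 3 adjusted over the list alone. Pnpla2, the adipose triglyceride lipase, was at 0.70 (adjusted p = 0.061), and its inhibitor G0s2 at 0.86 (adjusted p = 0.318), with 0.36 in its unused probe set. In the citric acid cycle list, 12 of 16 were above zero (median 0.10, camera adjusted p = 0.0011), with Fh1 called over all genes and adjusted over the list alone, and an adjusted p of 0.444 with an estimated correlation.

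Genes of glucose production and amino acid breakdown formed another group. Gluconeogenesis genes were higher as a list (8 of 11 above zero, median 0.16, camera adjusted p = 2.45e-05), with none called over all genes and 5 adjusted over the list alone. The adjusted p with an estimated correlation was 0.289. Ppargc1a, a coactivator of gluconeogenic genes, was at 1.37 (SE 0.26) and the aspartate aminotransferase gene Got1 at 1.07 (SE 0.21), both at an adjusted p of 0.051. G6pc, the glucose-6-phosphatase, was at 0.63 (adjusted p = 0.160) and Pck1, the PEP carboxykinase, at 0.40 (adjusted p = 0.185). FoxO targets repressed by insulin were higher (10 of 14, median 0.11, camera adjusted p = 1.24e-05, and adjusted p = 0.289 with an estimated correlation). Igfbp1 was the member called over all genes, and 5 passed adjusted over the list alone. Irs2, the insulin receptor substrate, was at 1.04 (adjusted p = 0.064). Urea cycle and amino acid breakdown genes were higher (17 of 24, median 0.16, camera adjusted p = 5.83e-06, and adjusted p = 0.424 with an estimated correlation). None was called over all genes, against 10 higher and 1 lower adjusted over the list alone, with the ornithine carrier gene Slc25a15 at 0.41 (adjusted p = 0.147).

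The ER chaperone list was lower. Of 19 members, 18 were below zero (median -0.28, camera adjusted p = 1.79e-06), with none called over all genes, 7 lower and 1 higher adjusted over the list alone, and an adjusted p of 0.444 with an estimated correlation. Derl3, of the ER-associated degradation machinery, was at -1.37 (SE 0.35, adjusted p = 0.166), the disulfide isomerase gene Pdia3 at -0.45 (adjusted p = 0.288) and the stress-response factor gene Xbp1 at -0.47 (adjusted p = 0.274). Dnajb9, a co-chaperone of the same list, was at 0.73 (adjusted p = 0.156). Glucocorticoid targets (median 0.21, camera adjusted p = 0.0051), the integrated stress response (0.07, adjusted p = 0.021) and periportal hepatocyte genes (0.14, adjusted p = 0.025) were higher. Their adjusted p values with an estimated correlation were 0.479, 0.289 and 0.444. Periportal genes averaged 0.39 around their means in CANA replicate 2 and at most 0.16 in the other CANA arrays, and without replicate 2 their median was below zero and the list did not pass. No member of these 3 lists was called over all genes, and adjusted over the list alone 2, 2 and 3 were higher. Etnppl, a periportal gene, was at 0.93 (adjusted p = 0.192), and Cebpb, of the stress response list, at 0.41 (adjusted p = 0.166). Thus 14 of 45 tested lists passed camera, 10 higher and 4 lower. None passed with an estimated correlation or by fry, where the lowest adjusted p were 0.289 and 0.104. Of the 14, 8 passed camera in all 13 fits that each left out 1 array; those of cholesterol synthesis, glycolysis, the citric acid cycle, glucocorticoid targets, the stress response and periportal genes did not. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.46 (adjusted p = 0.763).

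The count of 22 depended on single arrays. Without CANA replicates 1 to 4 it was 38, 5, 3 and 11, and without HFD replicates 1 to 4 it was 10, 6, 5 and 7. Lepr, Cyp4a31 and Fasn were called in all 13 fits that each left out 1 array, Ppp1r3c in 7, Igfbp1 in 6 and Ppp1r3g in 3. With the serial-number set, 1 to 8 against 9 to 14, as a term 46 genes were called, including all 22; CANA and HFD each had 2 arrays in either set, so the term left the differences as they were. Within serial numbers 1 to 8 alone 2 genes were called and within 9 to 14 none, where 738 and 1290 genes had an unadjusted p under 0.05. Dividing these 8 arrays by serial number in place of treatment called 41 genes.

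The second comparison asked what weight matching by caloric restriction changed against the continued diet. No gene passed the limma test (smallest adjusted p = 0.434), at an adjusted p of 0.10 the count was also 0, and 498 genes had an unadjusted p under 0.05 against 665 expected by chance. The genes at the ends of the ranking, which did not pass, included Olfr331 (-1.13, adjusted p = 0.434), Pramel33 (-0.77) and Gemin2 (-0.51) on the low side. On the high side were Krtap31-1 (0.59), Zfp764 (0.40), Bcl2a1a (0.39), Olfr518 (0.36) and Ess2 (0.30), and low-side E2f1 and Rprd1a were at -0.41 and -0.37, all at an adjusted p of 0.999. Olfr331, Pramel33 and Gemin2 in CR and Krtap31-1 and Bcl2a1a in HFD had means under 3.95, and Olfr518 in HFD one of 4.42, near the lower limit, so the size of these differences is uncertain. Olfr331 was the 1 gene called when the serial number or the serial-number set entered the fit.

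In CR against HFD, no gene of fatty acid synthesis, fat oxidation or glucose production passed. Cyp4a31 was at 0.92 (SE 0.28) and Ppp1r3c at 0.70 (SE 0.23), both at a limma adjusted p of 0.999 and named after their values were seen. Fasn was at -0.27 (SE 0.19, 95% interval -0.66 to 0.13), Srebf1 at -0.12 (SE 0.18) and Scd1 at -0.05 (SE 0.26), each with a limma adjusted p of 0.999. Igfbp1 was at 0.74 (SE 0.44), with 0.09 within serial numbers 1 to 8 and 1.73 within 9 to 14, Fgf21 at 0.20 (SE 0.24), Ppargc1a at 0.28 (SE 0.25), Pdk4 at 0.34 (SE 0.43) and Cyp7a1 at 0.20 (SE 0.31). G6pc was at 0.22 (SE 0.15), Pck1 at 0.12 (SE 0.10), Cpt1a at -0.04 (SE 0.13) and Slc5a2 at 0.05 (SE 0.12), all likewise at 0.999. The signs of Cpt1a, Fasn, Scd1, Srebf1 and Cyp7a1 turned in at least 1 alternative fit. The simulated data for this comparison had independent noise in each gene and 200 changed genes. In them, 98.2% of changes of 1 log2 unit and 57.0% of changes of 0.5 were called. These shares need not hold for the real arrays, which also differed by serial number.

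By camera, 8 of 45 lists passed in CR against HFD, 5 higher and 3 lower, with no member of any called over all genes or adjusted over the list alone. ER chaperones were lower (16 of 19 below zero, median -0.19, adjusted p = 0.0013, and adjusted p = 0.757 with an estimated correlation). Their mean deviation was -0.22 and -0.47 in CR replicates 1 and 5, and 0.06 to 0.33 in the other CR arrays against 0.09 to 0.30 in HFD. Pdia3 was at -0.34, Derl3 at -0.78 and the ER protein gene Creld2 at -0.54. Genes higher in male liver were lower (15 of 16 below zero, median -0.26, adjusted p = 0.0073, and adjusted p = 0.757 with an estimated correlation), with the major urinary protein gene Mup21 at -0.31. Their mean deviation was -0.51 and -0.59 in CR replicates 1 and 5, and 0.12 to 0.38 in the other CR arrays against 0.02 to 0.29 in HFD. Elovl3, the fatty acid elongase with the smallest p of that list, went the other way, at 0.81. Interferon-stimulated genes were lower (18 of 21, median -0.14, adjusted p = 0.010, and adjusted p = 0.739 with an estimated correlation), with the immunoproteasome gene Psmb9 at -0.24 and Irf7 at -0.22. Glucocorticoid targets were higher (11 of 14, median 0.16, adjusted p = 0.0073, and adjusted p = 0.757 with an estimated correlation), with the clock gene Per1 at 0.37 and Gadd45g at 0.80, where CR replicate 5 stood at 8.97 and the other CR arrays at no more than 7.46. Also higher were the lists of xenobiotic metabolism (median 0.13, adjusted p = 0.012), urea cycle and amino acid breakdown (0.07, adjusted p = 0.010), FoxO targets (0.13, adjusted p = 0.017) and gluconeogenesis (0.09, adjusted p = 0.049). Each of these 4 had an adjusted p of 0.757 with an estimated correlation. Members included the xenobiotic-metabolism genes Cyp2c54 at 0.37 and Ces2a at 0.21, Got1 at 0.43 and the FoxO target Cited2 at 0.50. The xenobiotic list had a mean deviation of 0.40 and 0.33 in CR replicates 1 and 5. It had -0.28 to 0.04 in the other CR arrays against -0.20 to 0.19 in HFD. None of the 8 passed in all 13 fits that each left out 1 array, and no list passed with the replicate number as a block. Replicate number 5 was in CR alone, so the block fit took nothing from CR replicate 5. Its result is thus not separate from that without this array. Without CR replicate 5 no list passed, and without CR replicate 1, CR replicate 4 or HFD replicate 1 the count was 5 each time.

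The third comparison set canagliflozin against the weight-matched group, and so also tests whether the effects of drug and restriction against HFD differ. Relative to CR, the treated livers had higher Lepr, Ppp1r3g, Ctcflos and Fbf1 and lower Ppp1r3c, Fasn, Thrsp and Pklr. Ppp1r3c fell by 2.11 on the log2 scale (SE 0.23, limma adjusted p = 0.0013), from 7.32 ± 0.32 in CR to 5.21 ± 0.31 in CANA (SD, n = 5 and 4). Lepr rose 4.00-fold, from 4.70 ± 0.50, also near the lower limit of the tested range, to 6.70 ± 0.57 (SE 0.26 on the log2 scale, adjusted p = 0.0064). Ppp1r3g rose by 1.39, from 4.60 (SE 0.25, adjusted p = 0.036), Ctcflos by 1.35 (SE 0.18, adjusted p = 0.0064) and Fbf1, a centriole protein gene, by 1.12 (SE 0.18, adjusted p = 0.020). Fasn fell by 1.14 (SE 0.19, adjusted p = 0.020), Thrsp by 1.09 (SE 0.17, adjusted p = 0.014) and Pklr by 0.97 (SE 0.17, adjusted p = 0.037). A smaller fall was that of Akr1c20, an aldo-keto reductase of a family of near copies (-0.90). Further rises were Tbc1d8 (0.88), Slc22a5 (0.80), Nnmt (0.77), Fh1 (0.73), Brap (0.58), Tmed5 (0.53) and Abcb4, the phosphatidylcholine exporter of bile (0.47). In all 20 genes passed, 13 higher and 7 lower. Of all tested genes, 390 (2.93%) had no overlap between the groups, where chance gives 1.59%, and 1122 had an unadjusted p under 0.05.

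Among 18 fatty acid synthesis genes 17 were lower than in CR (median -0.33, camera adjusted p = 9.81e-10, and adjusted p = 0.346 with an estimated correlation), with Fasn and Thrsp called over all genes and 8 adjusted over the list alone. Scd1 was at -1.31 (adjusted p = 0.064) and Srebf1 at -0.73 (adjusted p = 0.185). All 19 cholesterol synthesis genes were below zero (median -0.40, camera adjusted p = 1.94e-05, and adjusted p = 0.494 with an estimated correlation), with no single call, Lss at -1.11 and Fdps, the farnesyl diphosphate synthase, at -0.91. The glycolysis and fructolysis list was lower (median -0.17, camera adjusted p = 0.015, and adjusted p = 0.446 with an estimated correlation). Pklr was its member called over all genes, 3 were lower and 1 higher adjusted over the list alone, Khk was at -0.53 and Txnip at 0.90. In the glycogen list, which did not pass (camera adjusted p = 0.179), Ppp1r3b was at -0.85, with -0.92 in its unused probe set (unadjusted p = 1.91e-05), and Gys2, the liver glycogen synthase, at 0.41.

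PPAR-alpha targets were higher than in CR in 25 of 27 genes (median 0.33, camera adjusted p = 2.4e-08, and adjusted p = 0.494 with an estimated correlation), with none called over all genes, 6 adjusted over the list alone, Cyp4a31 at 1.23 and Crot at 0.36. Mitochondrial fatty acid oxidation was higher in 19 of 20 (median 0.20, camera adjusted p = 3.39e-07, and adjusted p = 0.446 with an estimated correlation), with Slc22a5 called over all genes and 1 adjusted over the list alone, Cpt2 at 0.25 and Cpt1a at 0.33. Also higher were the lists of lipid droplets (median 0.26, camera adjusted p = 0.0025), gluconeogenesis (0.16, adjusted p = 0.0073), FoxO targets (0.10, adjusted p = 0.013), urea cycle and amino acid breakdown (0.10, adjusted p = 0.013), the citric acid cycle (0.06, adjusted p = 0.013) and periportal genes (0.16, adjusted p = 0.032). Each had an adjusted p of 0.494 with an estimated correlation. Over all genes Fh1 alone of these was called; adjusted over the list alone 4, 4, 5, 5, 3 and 0 were higher and 1 amino acid gene lower. G0s2 was at 1.09 (0.25 in its unused probe set), Pnpla2 at 0.47, Ppargc1a at 1.09, Irs2 at 0.92, Igfbp1 at 1.85, G6pc at 0.41, Pck1 at 0.28 and Slc25a15 at 0.34, with adjusted p between 0.121 and 0.470. Nags, which makes the activator of the urea cycle, was at -0.42, and the succinyl-CoA ligase gene Sucla2 at 0.32. Fgf21 was at 1.02 (adjusted p = 0.165), Pdk4 at 1.16 (adjusted p = 0.483), Cyp7a1 at 0.26 (adjusted p = 0.872) and Slc5a2 at -0.15 (adjusted p = 0.780).

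Lists of other kinds also passed camera between the drug and restriction groups. Clock genes were lower (15 of 18, median -0.18, adjusted p = 0.013, and adjusted p = 0.446 with an estimated correlation), with Per3 at -0.35 and Bhlhe40 at -0.49. Xenobiotic metabolism genes were lower (17 of 23, median -0.19, adjusted p = 0.013, and adjusted p = 0.494 with an estimated correlation), with Ces2a at -0.35 and Cyp2c55 at -0.81, whose second probe set gave 0.50. Their mean deviation was 0.40 and 0.33 in CR replicates 1 and 5, and -0.28 to 0.04 in the other CR arrays against -0.15 to -0.02 in CANA. Acute phase genes (median 0.11, adjusted p = 0.032) were higher, with Saa2 at 1.00, as was oxidative phosphorylation (31 of 40, median 0.06, adjusted p = 0.048). With an estimated correlation these had an adjusted p of 0.494 and 0.661, and the median of the latter was below zero within serial numbers 9 to 14. Markers of other cell types moved in opposite directions. Endothelial markers were lower (14 of 15, median -0.18, adjusted p = 0.0072), with Fcgr2b at -0.34 and Oit3 at -0.28, while stellate cell and matrix genes were higher (12 of 18, median 0.13, adjusted p = 0.032), with Rgs5 at 0.58. Both had an adjusted p of 0.494 with an estimated correlation. No member of these lists was called over all genes, and 1 xenobiotic gene was lower adjusted over the list alone. In the bile acid list, which did not pass (camera adjusted p = 0.564), Abcb4 was called, Cyp8b1, a bile acid hydroxylase, was at 0.72 and the bile acid-induced repressor gene Nr0b2 at -0.67. By camera 17 of 45 lists passed, 11 higher and 6 lower, and none with an estimated correlation or by fry, where the lowest adjusted p were 0.346 and 0.135.

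The count of 20 was 9, 7 and 8 without CANA replicates 2, 3 and 4, and 8, 8 and 12 without CR replicates 1, 2 and 4. Lepr, Ctcflos, Fh1, Brap and Ppp1r3c were called in all 13 fits that each left out 1 array, Fasn in 8, Pklr in 5, Slc22a5 in 1 and Abcb4 in 0. The list count was 9 without CANA replicate 2, and 6 of the 17 lists passed camera in all 13 fits: fatty acid synthesis, cholesterol synthesis, PPAR-alpha targets, mitochondrial fatty acid oxidation, lipid droplets and the clock. With the serial-number set as a term 26 genes were called, against 5 within serial numbers 1 to 8 and 0 within 9 to 14, where 881 and 910 genes had an unadjusted p under 0.05.

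**Figure D3:**
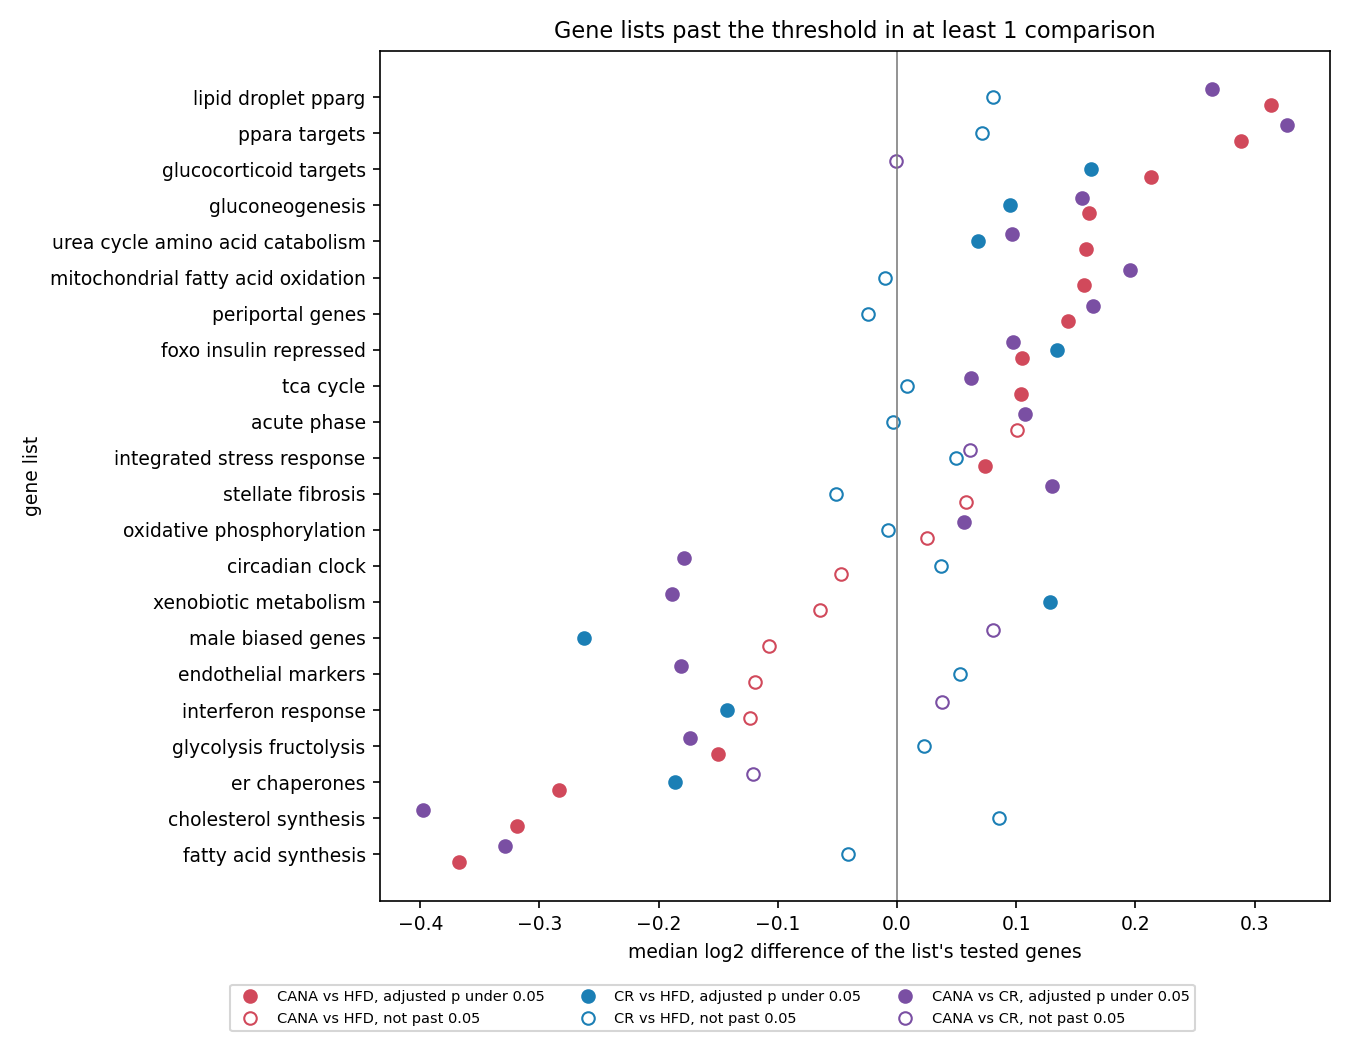
Median log2 difference of the tested genes (horizontal axis) for each gene list that passed camera in at least 1 comparison (vertical axis), with filled points where the adjusted p was under 0.05 and open points elsewhere. Fatty acid synthesis lies at -0.37 in CANA vs HFD and -0.33 in CANA vs CR, and at -0.04 in CR vs HFD.

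Between canagliflozin and both other groups, 15 genes were called with the same sign, 11 higher and 4 lower. Lists of these sizes drawn independently would share 0.0166 and 0.00263 genes, but the comparisons share the CANA arrays and so are not independent. Simulated unchanged groups shared at most 1 gene over 100 runs, but such groups have hardly any called genes to share. Neither figure is therefore a test of the 15. Genes called against both included Lepr, Ppp1r3g, Ctcflos, Slc22a5, Nnmt, Fh1, Fasn, Thrsp and Ppp1r3c. In CR against HFD these genes lay between -0.27 for Fasn and 0.70 for Ppp1r3c, whose SE was 0.23. When the CANA arrays were split so that each comparison used 2 of its own, 0 or 1 gene was called in both over the 6 splits. At an unadjusted p under 0.05, 137 to 188 genes were in both with the same sign, where independent lists would share 32.1 to 53.0. The count was 8, 5, 3 and 5 without HFD replicates 1 to 4, 1, 1 and 5 without CANA replicates 2, 3 and 4, and 5 and 6 without CR replicates 1 and 2. It was 21 with the serial-number set as a term, 1 within serial numbers 1 to 8 and 0 within 9 to 14.

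Across the 13308 genes, which are not independent replicates, the log2 differences CANA minus HFD and CR minus HFD correlated at a Pearson r of 0.467. The comparisons share the HFD arrays, and unchanged groups simulated against shared controls gave r between 0.498 and 0.551 over 100 runs, with a median of 0.528. The covariance was 0.0117 against a simulated median of 0.0097 and a highest simulated value of 0.0106, a difference of 0.0020. When the HFD arrays were divided into separate pairs for the comparisons, r lay between -0.17 and 0.141 over the 6 assignments, with a mean of 0.029, and the mean covariance was 0.0006. Simulations that shuffled whole arrays of residuals, which keep the correlation between genes, gave r from 0.222 to 0.843 and covariances from 0.0036 to 0.0264, so neither observed value stood outside them.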

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

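The tests of array order, of other cell types and of the serial-number axis were chosen only after the result was seen, while the counts of other splits of the arrays were planned.

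Canagliflozin-treated livers had 22 called genes against HFD, led by Igfbp1, Lepr and Cyp4a31 on the high side and Fasn and Ppp1r3c on the low side. Of the 35 splits of these 8 arrays, 2 gave as many genes, so chance was not excluded by this count. The other such split gave 41 and parted exactly serial numbers 1 to 8 from 9 to 14, which points to a structure of the samples. Every remaining split gave 0 genes. The mean serial number was 6.5 in CANA and 7.5 in HFD, so a linear trend along the array order could add little to the differences. With the serial number as covariate a median of 101% of the differences of the called genes was left, which this balance largely fixed in advance. The serial-number set as a term, with 22 of 22 still called, decided nothing, since both groups had 2 arrays in each set. For the called genes as a set, a changed share of the cell types with a tested marker list was argued against. The largest median of these 8 lists was 0.119 in size, that of endothelial markers at -0.12, against a median size of 1.03 for the called genes. The called genes were picked for clear differences, so single genes from another cell type were not excluded. Neutrophil, blood and pancreas markers had only 3, 1 and 3 tested genes and were not used. An effect of the drug itself stays open as a hypothesis.

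The arrays split by serial number along the first principal component, with lower small nucleolar RNA genes such as Snord52 (-0.14 per serial number, limma adjusted p = 0.0042) at later numbers and a higher cholesterol synthesis list (median slope 0.07, camera adjusted p = 1.46e-18, and adjusted p = 0.474 with an estimated correlation). Group membership alone could not part the serial-number sets, since every group had arrays in both. The groups held 22.3% of the variance of the component and the serial number 49.9%, which does not exclude a share of the groups in it. CANA replicates 1 and 2 scored -9.97 and 5.19, against -18.95 and -14.27 in HFD replicates 1 and 2. CANA replicates 3 and 4 scored 17.41 and 11.99, against 2.79 and 4.565 in HFD replicates 3 and 4. The CR arrays ran from -10.12 to 10.69. These scores were compared after they were seen, without a test. A drifting recovery of small RNA may contribute: 11.4% of random lists had a median slope as low as or lower than that of 142 microRNA and small nuclear RNA genes, which leaves it open. Collection at a changing clock time may contribute too: the difference between clock genes of opposite phase lay at percentile 96.2 of random splits of genes, which also leaves it open. No biological explanation beyond the groups and the clock time was tested.

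Single arrays stood apart from the rest of their group for 12 of the 252 combinations of named gene and group. Chance gives about 1 in 20, so this count is no more than chance gives. In HFD, replicate 1 had Akr1c20 at 5.87 against 6.49 to 6.60 and Per3 at 6.83 against 7.08 in the nearest array, and replicate 4 had Cyp2c55 at 6.27 against at most 5.97. In CANA, replicate 1 had Nr0b2 at 7.76 against at most 6.72, replicate 2 had Cited2 at 7.21 against at least 7.96, and replicate 3 had Cyp4a31 at 8.60 against at most 7.66. CANA replicate 4 had Bcl2a1a at 4.20 against at most 4.05 and Krtap31-1 at 4.22 against at most 3.91. In CR, replicate 3 had Slc5a2 at 3.99 against at least 4.41, and replicate 5 had Gadd45g at 8.97 against at most 7.46. CR replicate 4 had Gemin2 at 3.67 against at least 3.91 and Gys2 at 10.56 against at least 10.96.

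Among 7832 probe sets without a single gene symbol, which the comparisons did not use, 2 passed in limma for CANA against HFD, 1 higher and 1 lower, and 435 had an unadjusted p under 0.05 against 392 by chance. For CR against HFD and CANA against CR 0 passed in limma, with 345 and 446 at an unadjusted p under 0.05.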

How the results depend on the processing

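The alternatives with the serial-number sets were chosen only after the result was seen. The 22 genes of CANA against HFD became 12 without a filter on dim genes, 39 with the 60th percentile filter, 14 with eBayes with trend and robust, 56 at an adjusted p under 0.10, 40 with the serial number as covariate and 46 with the serial-number set as a term. They were 2 with serial numbers 1 to 8 only and 0 with 9 to 14 only, where fewer samples were fitted. Leaving out each array gave 3 to 38, the lowest without CANA replicate 3 and the highest without CANA replicate 1. The 0 genes of CR against HFD became 1 with the replicate block, with the serial number as covariate and with the serial-number set as a term, and stayed 0 without any array, with limma throughout. The 20 genes of CANA against CR became 34 at an adjusted p under 0.10, 5 with serial numbers 1 to 8 only and 0 with 9 to 14 only, and 7 without CANA replicate 3 to 23 without CR replicate 5. The 15 genes called against both became 8 without a filter, 25 at an adjusted p under 0.10, 1 and 0 with serial numbers 1 to 8 and 9 to 14 only, and 1 without CANA replicate 2 to 19 without CR replicate 5. With an estimated correlation 0 lists passed in each comparison, and by fry also 0, where 7, 2 and 4 lists had an unadjusted p under 0.05 with an estimated correlation. The 8 lists of CR against HFD became 0 with the replicate block and ranged from 0 without CR replicate 5 to 12 without CR replicate 3. The block fit also took nothing from CR replicate 5, the only array with that number. The 17 lists of CANA against CR became 8 with serial numbers 9 to 14 only and ranged from 9 without CANA replicate 2 to 18 without CANA replicate 4. With the replicate block 29, 1 and 17 genes were called in the 3 comparisons. By the labels, arrays with the same replicate number shared that number and had neighbouring serial numbers. Their deviations correlated at -0.15 to 0.296, with a median of 0.114 against -0.0481 for different numbers and 7 of 12 pairs over 0.1. Of the 13 arrays, 8 correlated best with their own number. CR replicate 3 was in the other serial-number set from CANA and HFD replicate 3, and these pairs were at -0.138 and -0.15. A pairing by replicate number therefore cannot be told apart from the serial-number sets. The correlation of the effects was 0.378 to 0.560 over the arrays left out.

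Signs turned with serial numbers 1 to 8 only for Slc5a2 in CANA against HFD (0.16) and against CR (0.0642), and in CR against HFD for Cpt1a (0.0255), Fasn (0.0679) and Srebf1 (0.14); Scd1 turned with 9 to 14 only (0.33). Leaving out 1 array took Cpt1a in CR vs HFD from -0.13 without CR replicate 5 to 0.0193 without CR replicate 3, Scd1 from -0.24 to 0.14 without the same arrays, and Cyp7a1 from -0.0469 without HFD replicate 1 to 0.36 without CR replicate 1. None of these was past the threshold. Apart from the effects of fewer samples, fewer genes or another threshold, the cause was not tested. Over the named genes, 1836 values under the other alternatives kept their sign and side of the threshold, 91 lost and 50 gained a call, and 6 changed sign. With 1 array left out, 1549 values kept both, 151 lost and 22 gained a call, and 7 changed sign. The cholesterol_synthesis list in CANA vs HFD, which also moved with the serial number, had a median of -0.245 with the serial number as covariate (camera adjusted p = 0.0056, against 0.0035 without it). The oxidative_phosphorylation list in CANA vs CR passed camera in 11 of 21 other settings, and its median turned to -0.0173 with serial numbers 9 to 14 only (adjusted p = 0.774). The periportal_genes list in CANA vs HFD had a median of -0.0058 without CANA replicate 2 (adjusted p = 0.243). The signal over background limits dim genes such as Slc5a2.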

Other observations

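No test in this part was chosen only after the result was seen, except the looks at single arrays of CANA and CR. Immediate-early genes, which respond within minutes to stimulation, had a median of 0.16 in CANA against HFD with 11 of 13 members above zero, and did not pass camera (adjusted p = 0.052). Their mean deviation was 0.64 in CANA replicate 3, against -0.08 to -0.03 in the other CANA arrays and -0.21 to 0.24 in HFD. Genes of ketone body synthesis had a median of 0.07 (adjusted p = 0.065) and those of oxidative phosphorylation 0.02 (adjusted p = 0.056). Kupffer cell markers, of the resident macrophages of liver, had medians of 0.09 in CANA against HFD, -0.06 in CR against HFD and 0.14 in CANA against CR. None of the 3 passed camera, with adjusted p of 0.474, 0.520 and 0.103.

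Genes higher in male liver were not alike among the CR arrays. Their mean deviation from the gene means was -0.51 in CR replicate 1 and -0.59 in CR replicate 5, against 0.18, 0.38 and 0.12 in CR replicates 2, 3 and 4. Genes higher in female liver had 0.33 and 0.86 in CR replicates 1 and 5, against -0.21, -0.73 and -0.09 in the others. ER chaperone genes had -0.22 and -0.47 in the same pair, against 0.33, 0.06 and 0.15. The male-biased list had an adjusted p of 0.144 without CR replicate 1 and 0.318 without CR replicate 5, and the ER chaperone list 0.151 without CR replicate 5. Over their alternatives these adjusted p ran from 1.94e-05 to 0.757 and from 6.91e-08 to 0.757.

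The genes that separated CANA from CR were more than other splits gave. Of 100 splits of these arrays, 1 gave as many genes, the real one with 20 against at most 3 in the others. Regrouping the arrays at random thus rarely gave such a count, which does not bear on single genes. For its lists, 2 of 100 gave as many by camera, and the other 1 gave more, 19 against 17; none of the 17 passed with an estimated correlation (lowest adjusted p = 0.346) or by fry (lowest adjusted p = 0.135). For genes called against both other groups, 1 of 100 assignments gave as many, the real one with 15 against 0. For CANA against HFD, 6 of 35 splits gave as many as 14 lists, with at most 18, so chance was not excluded. For CR against HFD, 40 of 100 splits gave as many lists as 8, with at most 21, so chance was not excluded for the lists. A count of 0 genes in limma is reached by every split by construction (100 of 100, with at most 3 genes), so this count decided nothing, a reading set only after the result was seen.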
